A study of Mus musculus with 13 samples.

How the data were processed

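Small RNA libraries were made from mature cauda epididymal sperm (2 control, 2 AAE) and RNA-seq libraries with a Nugen Trio kit from groups of 2-cell embryos (3 control, 3 AAE, 3 AAS), per the labels' protocols. The submitters' processing notes name FastQC, Bowtie, Bowtie2, edgeR and the build mm9 for sperm, and HISAT2 2.0.4, DESeq2 and mm10 for embryos, with no role or order. The sperm files deposited by the authors hold raw read counts per RNA sequence entry, 69575 entries in all, and the treatment of reads that match several entries is not stated. Among entries over 100 counts, 10.6% of snRNA, 7.17% of tRNA and 0.0% of miRNA entries had another entry with near-identical counts and may share its reads. Entries that share only part of their reads can escape this check. The embryo files deposited by the authors hold FPKM per transcript, and transcripts at 0 are not listed. A gene missing from a library's file was taken as 0, which can also be a failed estimate. The deposited series tables hold the authors' log2 fold changes and p-values, which were used only beside the values computed here. Of 16739 embryo gene IDs, 16703 matched the RefSeq gene table of GRCm38, from which coordinates were taken; no sperm coordinates are given.

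Sperm counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, filterByExpr), with DESeq2 1.42.0 as another test. Class shares are percentages of all counts summed over entries, compared with a two-sided exact permutation test. Reads counted in several entries can raise the share of their class. FPKM of the transcripts of a gene were summed, genes with a mean of 1 FPKM or more kept, and log2(FPKM + 1) of all 9 libraries fitted at once with limma 3.58.1 (eBayes with trend). Embryo fold changes are on this scale, which understates the change of genes with low values. The design had allowed for counts, which the embryo files do not hold. All tests were two-sided, with Benjamini-Hochberg adjustment at 0.05.

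Gene lists (13 for sperm, 20 for embryos) were tested with camera at a preset correlation of 0.01, beside fry, which tests whether the genes of a list move on balance one way, and camera with an estimated correlation. Fry compares no list with other genes. Lists needed 3 measured members, and a variance trend was used; both were set after the data had been seen, and exploratory fits preceded the final ones. No mitochondrially encoded gene and 1 blood marker passed the filter, so these lists were not tested. The lists, the groups, the tests and most alternatives were fixed before the data were examined. The rule for named genes took those past the threshold without overlap and, as none passed, the 10 with the smallest p, plus the 3 members of each list with the smallest p. Members are printed for called lists and some others, and fewer than 3 for some of these, a narrowing made after the values were seen. Sperm RNAs needed a mean count of 50 or more to be named among the 10.

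Alternatives were other scaling, filters, pseudocounts and tests, a replicate block, leaving out each library, and, chosen after seeing the data, leaving out both embryo libraries with the lowest correlation, list tests under settings first planned for genes alone, RNA classes as sets and a simulation with group variances. In simulated data with 200 changed genes, the embryo test of 9766 genes recovered 22.7%, 65.7% and 91% of genes changed by 1, 2 and 3 on the log2 scale, with 3 false calls. The sperm test of 21008 RNAs recovered 6.06%, 74.6% and 97%, with 15 false calls. Changed embryo genes were drawn only from those with a mean log2(FPKM + 1) over 2. Changed sperm RNAs were drawn only from those with a mean count of 50 or more. Recovery below these levels was not simulated. Embryo values were drawn independently with 1 spread per gene for all groups. The mean variances of the data were 0.216 in control, 0.442 in AAE and 0.536 in AAS embryos. The biological coefficient of variation in sperm was 0.242, so differences near 1 on the log2 scale were mostly below what 2 libraries per group can call. Embryo depth is unknown, so no counting error is given. AAS sperm were not analysed here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6.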

Results

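Small RNAs were sequenced from mature sperm of the cauda epididymis, the last segment of the duct in which sperm mature, and RNA was sequenced from groups of 2-cell embryos made by in vitro fertilisation. The fathers were Swiss mice that had received acrylamide, a reactive compound formed in heated starchy food, or the vehicle (PBS) by intraperitoneal injection. The dose was 25 mg/kg per day on 5 days. Sperm collected 3 days after the last injection had been in the epididymis during exposure (AAE), and sperm collected 24 days after it had been spermatocytes in the testis (AAS). The sperm data held 2 control and 2 AAE libraries, with no AAS library, and the embryo data held 3 control, 3 AAE and 3 AAS libraries. Summed over all entries, the sperm libraries held 14571528 and 13445938 counts in control and 15356820 and 12810223 in AAE. A read may be counted in several entries, so these are not totals of reads. The embryo files give FPKM only, so their depth is unknown. They listed 13933, 13675 and 14392 genes in the control libraries, 12563, 13914 and 11625 in AAE, and 12225, 12173 and 12673 in AAS. The labels do not say that replicates are separate animals, so the p-values measure the spread between these samples.

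The first comparison asked whether epididymal exposure was followed by a different small RNA content of sperm. In both AAE libraries miRNAs and snoRNAs took a larger share of the counts than in both control libraries. The shares are given with the SD of 2 libraries per group. The miRNA share was 6.44% ± 1.54 (SD, n = 2) in AAE and 3.79% ± 0.632 (SD, n = 2) in control, a ratio of 1.70. The snoRNA share, of RNAs that guide modification of ribosomal RNA, was 5.20% ± 0.690 and 3.38% ± 0.398 (SD, n = 2 each), and the snRNA share 4.74% ± 0.557 and 3.37% ± 0.290. Ribosomal RNA fragments took 12.6% ± 1.06 in AAE and 16.5% ± 2.01 in control. Fragments of tRNA, the most abundant class, took 49.0% ± 4.31 and 52.6% ± 1.26, and piRNAs 19.9% ± 3.86 and 18.7% ± 1.75. The miscellaneous RNA share was 1.98% ± 0.114 in AAE and 1.51% ± 0.477 in control, and the remaining entries took 0.0920% ± 0.0197 and 0.182% ± 0.0016. The two-sided exact permutation p was 0.333 for miRNA, snoRNA, snRNA, rRNA, miscellaneous and remaining RNAs, 0.667 for tRNA and 1 for piRNA, and 2 against 2 libraries cannot give less than 0.333. Without the most abundant entry of each class the ratio of the remaining entries moved from 0.507 to 0.810.

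**Figure D1:**
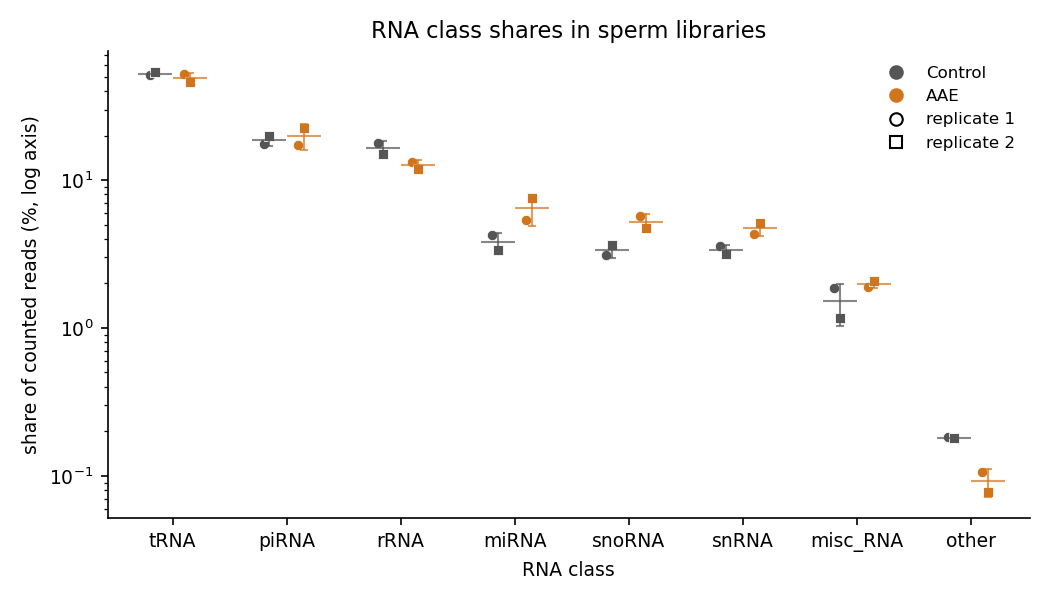
Share of counted reads (%, log axis) in each RNA class per sperm library; points are libraries, horizontal lines group means and bars the SD (n = 2). Both AAE libraries (5.35% and 7.53% miRNA) lie above both control libraries (4.23% and 3.34%).

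Among single sperm RNAs, the smallest p-values belonged to small nuclear and nucleolar RNAs with higher values in AAE and to piRNAs with lower values. U17a and U17b, which act in ribosomal RNA processing, had log2 fold changes of 1.66 (SE 0.364) and 1.69 (SE 0.390), the spliceosomal RNA U1 1.36 (SE 0.301) and Snora21 1.33 (SE 0.316). U17a stood at 43.9 ± 15.2 CPM in AAE and 13.8 ± 1.08 in control (SD, n = 2 each). The piRNAs piR-130593, piR-4797, piR-103587, piR-4798, piR-134260 and piR-124229 had log2 fold changes of -1.15, -0.9997, -1.01, -1.02, -1.01 and -1.16. None of these passed the test: of 21008 RNAs, 0 had an adjusted p under 0.05 in edgeR's quasi-likelihood test (smallest adjusted p = 0.945). At an unadjusted p under 0.05 there were 1012 (544 higher, 468 lower), where 1050 would arise by chance, and DESeq2 gave 0 calls and 121 at unadjusted p under 0.05. The p-values in the deposited table give 4 calls after Benjamini-Hochberg adjustment. Of the 1012, miRNAs gave 39 higher and 4 lower, snoRNAs 42 higher and 0 lower, tRNAs 1 higher and 13 lower, and piRNAs 427 higher and 434 lower. The count of calls was 7 without control replicate 1, 411 (31 higher, 380 lower) without AAE replicate 1 and 139 (133 higher, 6 lower) without AAE replicate 2. It was 16 with no filter on low counts and 1 with library totals as the only scaling, which moved the median of all RNAs to 0.36 on the log2 scale.

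Grouped by family, miRNAs were higher in AAE sperm relative to other RNAs in 8 of the 12 lists tested with camera at a preset correlation. The preset was 0.01, and the estimates for these 8 lists ran from 0.289 to 0.872. The preset p-values thus rest on a correlation far below the estimates. With an estimated correlation no list was called, with an adjusted p = 0.581 for the X-linked cluster and 0.548 for the other 7, and fry, which tests a list without reference to other RNAs, gave adjusted p = 0.5565 for the X-linked cluster and leukocyte markers and 0.542 for the other 6. The list of epithelial miRNAs, the miR-200 family with others such as miR-205, is called the miR-200 list here. It was higher (median log2 fold change 0.79, 13 of 13 entries positive, camera adjusted p = 4.93e-08), with miR-205-5p at 4.95 ± 2.38 CPM against 1.93 ± 0.206 and values of 1.06 for miR-141-5p and 0.80 for miR-200a-5p. The miRNAs abundant in the epididymis were higher (median 0.46, 30 of 31 positive, adjusted p = 1.18e-06), although their mean was -0.0134 with miRNAs scaled to each other, among them miR-10b at 0.87, miR-145 at 0.80 and miR-26b-5p at 0.70. The miR-34 and miR-449 family of germ and ciliated cells was higher (median 0.75, 9 of 10 positive, adjusted p = 0.000123), with miR-34a at 1.46, miR-34a-5p at 1.47 and miR-449c-3p at 0.94. Mean counts were low for miR-34a (20.75), miR-34a-5p (12.25) and miR-449c-3p (23.75), as for miR-141-5p (15.5) and miR-145 (21.25). The entries miR-34a and miR-34a-5p can share reads. The X-linked cluster expressed in spermatogenic cells was higher (median 0.31, 28 of 32, adjusted p = 0.000249), although its mean was -0.11 with miRNAs scaled to each other, with miR-742-3p at 1.08, miR-742-5p at 0.72 and miR-463-3p at 0.59. The let-7 list (0.52, 13 of 13, adjusted p = 0.000287), the miR-17-92 list (0.43, 11 of 13, adjusted p = 0.000368) and the miR-30 list (0.57, 12 of 12, adjusted p = 0.000695) were higher too, and the members with the smallest p were let-7i at 1.40, let-7c-2-3p at 0.73, miR-98-5p at 0.86, miR-17-5p at 0.85, miR-106b-5p at 0.81, miR-20a-5p at 1.08, miR-30b at 1.15, miR-30e-5p at 0.75 and miR-30b-5p at 1.06. The leukocyte markers were higher (median 0.30, 5 of 5, adjusted p = 0.0162), with miR-146a-5p at 0.92, miR-146b-5p at 0.96 and miR-142a-3p at 0.30. Leaving out 1 library moved 15 of the 34 named sperm RNAs by over 1.5 times. The lowest values were -0.21 for miR-142a-3p, 0.22 for miR-146b-5p, 0.29 for miR-200a-5p, 0.27 for miR-30e-5p, 0.43 for miR-17-5p, 0.40 for miR-10b, 0.44 for miR-26b-5p and 0.68 for miR-205-5p, each without AAE replicate 1. They were 0.29 for let-7c-2-3p, 0.38 for miR-449c-3p, 0.59 for miR-742-3p, 0.333 for miR-463-3p and 0.40 for miR-106b-5p without control replicate 2, where miR-142a-3p was at -0.195, and 0.31 for miR-98-5p and 0.45 for miR-145 without control replicate 1. Adjusted over the list alone, 0 members of any list were called. Red blood cell markers (adjusted p = 0.0601), miRNAs reported in paternal stress (0.0635), miR-29 (0.142) and the Dlk1-Dio3 cluster (0.784) were not called, and the muscle markers were not measured.

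With miRNAs scaled to each other, 2 lists were called, the miR-34 and miR-449 family and the miR-200 list, and the adjusted p was 0.553 for let-7, 0.217 for the X-linked cluster, 0.339 for miR-30 and 0.585 for miR-17-92, the epididymal list and leukocyte markers. Without AAE replicate 1, the same 2 lists were called, and the adjusted p was 0.872 for the X-linked cluster (mean -0.0486), 0.175 for let-7, 0.230 for miR-17-92 and for miR-30, 0.417 for the epididymal list and 0.584 for leukocyte markers. Without control replicate 2, 3 lists were called, and the adjusted p was 0.318 for miR-34 and miR-449, 0.917 for the X-linked cluster, 0.485 for miR-17-92 and leukocyte markers and 0.534 for miR-30. The TMM factor, which corrects for composition, was 1.65 in AAE replicate 2 and 0.930, 0.903 and 0.722 in the other 3 libraries. List means given here use these factors. As CPM over all counts, without them, the epididymal list was higher in AAE replicate 2 (17132) than in AAE replicate 1 (13020). Without AAE replicate 1 the mean moved from 0.797 to 0.434 for the miR-200 list, from 0.747 to 0.447 for miR-34 and miR-449 and from 0.467 to 0.0424 for the epididymal list. It moved from 0.551 to 0.176 for let-7, from 0.4498 to 0.1105 for miR-17-92, from 0.555 to 0.185 for miR-30 and from 0.474 to 0.120 for leukocyte markers. Without control replicate 2 it was 0.453 for miR-34 and miR-449, 0.0468 for the X-linked cluster, 0.2195 for miR-17-92, 0.359 for miR-30 and 0.304 for leukocyte markers. It was higher without AAE replicate 2 for let-7 (0.838), the X-linked cluster (0.591), the epididymal list (0.771) and leukocyte markers (0.870), and without control replicate 1 for the X-linked cluster (0.633), miR-17-92 (0.712) and leukocyte markers (0.778). Entries such as miR-30b and miR-30b-5p can share reads.

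**Figure D2:**
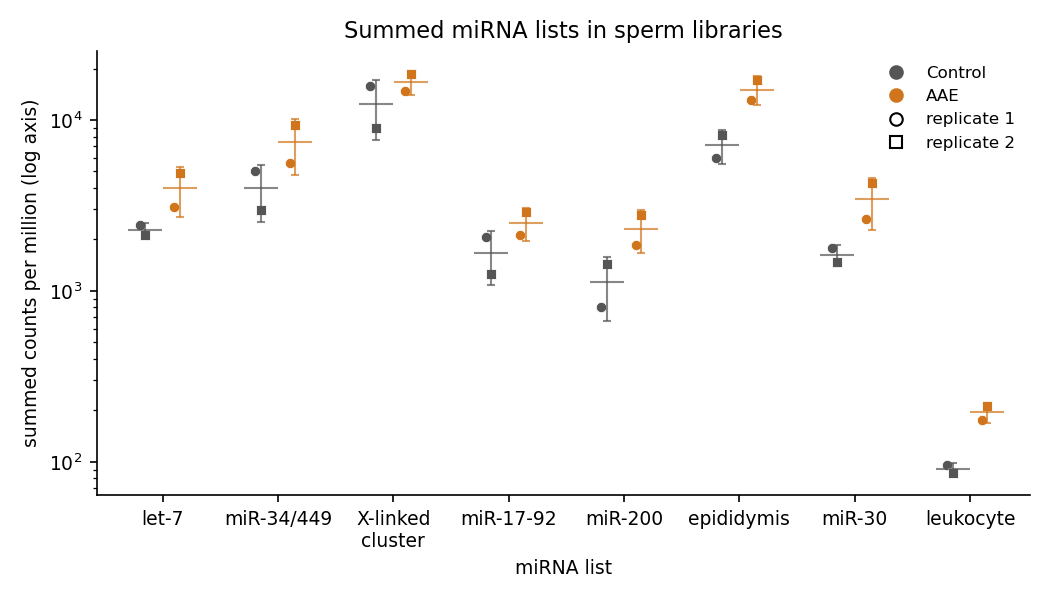
Summed CPM over all reads (log axis) of 8 miRNA lists per sperm library; points are libraries, horizontal lines group means and bars the SD (n = 2). The epididymal list summed to 15080 in AAE and 7100 in control, and the X-linked cluster to 16730 and 12380, where AAE replicate 1 lies below control replicate 1; with miRNAs scaled to each other both lists had negative means, -0.0134 and -0.11.

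The second comparison set embryos of AAE fathers against control embryos. Relative to other genes, those of the ribosome were lower in AAE embryos and maternal transcripts slightly higher, by camera at a preset correlation. The preset was 0.01, and the estimate was 0.767 for ribosomal proteins, 0.410 for biogenesis, 0.0567 for maternal and 0.264 for cumulus genes. With an estimated correlation the adjusted p was 0.914 for both ribosome lists and 0.602 for the maternal and cumulus lists. Fry gave 0.968 for each of these 4. The ribosomal protein mean was -0.32 and turned to 0.18 without AAE replicate 3 and to 0.05 without control replicate 1. The 79 cytosolic ribosomal protein genes had a median log2 fold change of -0.29 (62 negative, camera adjusted p = 0.0165), with Rps6 at -0.64 and Rpl21 at -0.96. Rpl38 was at 28.97, 24.4 and 6.13 FPKM in control and 8.73 and 18.64 in AAE replicates 1 and 2, and was not listed in AAE replicate 3, without which its log2 fold change moved from -1.61 to -0.35. The 48 genes of ribosome biogenesis had a median of -0.29 (40 negative, adjusted p = 0.0165), with Utp14a at 5.57 ± 3.68 FPKM against 15.8 ± 5.91 (SD, n = 3 each), Utp3 at -0.65 and Pes1 at -0.59. Maternal oocyte genes had a median of 0.10 (30 of 48 positive, adjusted p = 0.00769), with Oas1d at 117 ± 3.63 FPKM against 81.1 ± 10.3 (SD, n = 3 each), Nlrp9b at 0.52 and Spin1 at 0.30. The 3 measured cumulus and granulosa cell markers, Nr5a2, Cyp19a1 and Amhr2, stood at -0.67, -0.89 and -0.93 (adjusted p = 0.0165), where Nr5a2 is also a transcription factor of early embryos and Amhr2 was not listed in AAE replicates 1 and 3.

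Of the single genes, none passed the test in AAE embryos. The smallest p-values belonged to Tox, a chromatin protein (1.36, SE 0.3295), F8a (1.42), Trappc2l of a vesicle tethering complex (1.79, not listed in control replicate 2), Rpl3l (3.06, at 22.3 ± 29.4 FPKM against 0.570 ± 0.159, SD, n = 3 each), Slc25a35 (-1.87), Sec11c of the signal peptidase (-1.58), Chchd4 of mitochondrial import (1.67, not listed in control replicate 2), Nfyb of the NF-Y factor (-1.58), Tarm1 (-1.68) and Mxd4 (1.24). Of 9766 genes, limma called 0 (smallest adjusted p = 1). At an unadjusted p under 0.05 there were 206 (87 higher, 119 lower), where 488.3 would arise by chance. This count was 317 with only the 2 groups fitted and 519 with array quality weights, so it depends on the fit. The main fit shares 1 spread per gene over groups of unlike variance. A count below chance therefore does not by itself show absent effects. The deposited DESeq2 table calls 15, among them Tox, F8a and Rpl3l, and not the other genes with the smallest p. Groups did not overlap for 833 genes (8.53%), where chance gives 10%. Adjusted over the list alone, 0 genes of any list were called. Among p53 targets Cdkn1a stood at -0.69, Ddb2 at -0.71 and Polk at 0.84. Among oxidative stress genes Nqo1 was at 0.93, Mgst3 at 0.73 and Prdx6 at -1.07, and among DNA repair genes Xrcc3 at 0.83 and Polb at -0.76. The 2-cell genes Usp17la, Spz1 and Gm12794 stood at 0.67, -0.69 and -0.29. The list adjusted p was 0.795 for p53 targets, 0.681 for oxidative stress, DNA repair and imprinted genes, 0.411 for 2-cell, heat shock, oxidative phosphorylation and pluripotency genes, 0.600 for chromatin, 0.879 for apoptosis, 0.875 for small RNA machinery and 0.795 for glycolysis, mitosis and spermatid genes. The spermatid list had a median of -0.10 and a mean of 0.14, and DNA repair a median of -0.05 and a mean of 0.01.

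The list calls of AAE embryos depended on single libraries, and leaving out 1 library moved 15 of the 33 named genes by over 1.5 times. Without AAE replicate 3, Prdx6 was at -0.40, Polb at -0.35, Nr5a2 at -0.30, Utp14a at -0.89, Utp3 at -0.39, Rpl21 at -0.61, Spz1 at -0.40 and Nlrp9b at 0.28. Mgst3 was at 0.30 without control replicate 3, and Rpl3l at 1.99 and Pes1 at -0.39 without AAE replicate 2. Without AAE replicate 1 Cyp19a1 was at -0.58, Amhr2 at -0.61 and Gm12794 at -0.17. Without AAE replicate 3 no list was called, the mean of the ribosomal protein genes was 0.18 (adjusted p = 0.465), and the adjusted p was 0.999 for biogenesis, 0.465 for maternal and 0.422 for cumulus genes. Without control replicate 1, 2 lists were called, the mean of the ribosomal protein genes was 0.05 (adjusted p = 0.927) and biogenesis had an adjusted p = 0.453. Without control replicate 2, 2 lists were called, with an adjusted p = 0.189 for ribosomal proteins and 0.0553 for cumulus genes. The cumulus list had an adjusted p = 0.0556 without control replicate 3 and 0.101 without AAE replicate 1. The maternal mean moved from 0.0960 to 0.0289 without control replicate 3, 0.0563 without AAE replicate 2, 0.152 without control replicate 1 and 0.164 without AAE replicate 1. The ribosomal protein mean was -0.77 without control replicate 3 and -0.71 without AAE replicate 2, and that of biogenesis moved from -0.30 to -0.45 without AAE replicate 2. AAE replicate 3 listed the fewest genes, 11625, and had a median correlation of 0.872 with the other libraries. With no FPKM filter 2 lists were called (ribosomal proteins adjusted p = 0.303, biogenesis 0.211), and with array quality weights 0, settings chosen for lists after seeing the data.

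The third comparison set embryos of AAS fathers against control embryos. Ribosomal protein genes were lower in AAS embryos relative to other genes: 78 of 79 were negative, the median log2 fold change was -0.89 against -0.11 for all genes, and camera at a preset correlation gave an adjusted p = 5.26e-11. With an estimated correlation the adjusted p was 0.737 for this and the other 2 lists called, and fry gave 0.478 for ribosomal proteins, 0.469 for oxidative phosphorylation and 0.493 for ribosome biogenesis. Rpl21 was at 8.49 ± 5.08 FPKM against 29.1 ± 9.38 in control, Rps19 at 8.81 ± 6.07 against 38.2 ± 25.3 and Rpl5 at 7.58 ± 7.38 against 24.6 ± 7.70 (SD, n = 3 each). Nuclear genes of oxidative phosphorylation were lower (median -0.48, 58 of 70 negative, adjusted p = 0.00137), with Cox7c at 0.623 ± 0.492 FPKM against 6.33 ± 1.29 and Ndufa10 at 15.2 ± 3.12 against 30.1 ± 8.15 (SD, n = 3 each). Ndufa5 was not listed in any AAS library or in AAE replicates 1 and 3, and was at 4.78, 0.70 and 5.96 FPKM in control, which without counts cannot be read as a change. Ribosome biogenesis genes were lower (median -0.52, 41 of 48 negative, adjusted p = 0.0167), with Npm1 at -0.64, Nop58 at -0.86 and Rrp12 at 0.93.

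Single genes with the smallest p in AAS embryos were lower than in control. Fam162a, a mitochondrial protein, was at 0.283 ± 0.216 FPKM against 6.81 ± 1.86 (log2 fold change -2.59, SE 0.453), and Immp1l, a peptidase of the inner mitochondrial membrane, at 67.1 ± 1.94 against 144 ± 31.9 (-1.07, SE 0.198). Vkorc1 of the vitamin K cycle was at 17.1 ± 7.17 against 57.7 ± 4.15 (-1.77), and Sycp3, a protein of the synaptonemal complex of meiosis, at 83.2 ± 5.47 against 147 ± 16.4 (-0.81). The others were Stxbp3 (-2.12), Ccl3 (-2.15), Kin (-1.53), Ppp2r5c (-0.89), Dnajc19 of mitochondrial import (-1.99) and the X-linked Xlr4b (-1.13); Ccl3 was not listed in AAS replicates 2 and 3, nor Dnajc19 in AAS replicate 1. None passed: limma called 0 of 9766 genes (smallest adjusted p = 0.659), with 602 at an unadjusted p under 0.05 (149 higher, 453 lower). The deposited table calls 35, among them Fam162a, Immp1l, Vkorc1, Stxbp3 and Kin, and not Sycp3, Ccl3, Ppp2r5c, Dnajc19 or Xlr4b. Every AAS library listed fewer genes than every control library. Between 1.485% and 3.328% of the tested genes were taken as 0 in AAS libraries, against 0.3072% to 0.4096% in control. How far this adds to the genes with lower values was not tested. Groups did not overlap for 1281 genes (13.1%, chance 10%). Adjusted over the list alone, 1 gene was called, Sycp3 among the 7 spermatid and sperm markers, a list for which fry gave an adjusted p = 0.0222 and camera 0.126, and which also held Oaz3 at -1.44 (not listed in AAS replicate 2) and Odf2 at -0.20. Among DNA repair genes Xrcc3 was at -1.45 and Blm at -0.59, and among mitosis genes Pttg1 at -0.72, Kif23 and Birc5 at -0.66. The 2-cell genes Usp17le, Zscan4d and Gm5662 stood at 1.36, -0.58 and -0.69, the maternal genes Dppa3, Nobox and Npm2 at -0.50, 0.46 and -0.57, and the p53 targets Ccng1, Ercc5 and Trp53inp1 at -0.93, -0.39 and 0.47. The list adjusted p was 0.126 for mitosis, 0.419 for cumulus, 0.820 for maternal genes and p53 targets, 0.962 for glycolysis, and 0.5001 for 2-cell, DNA repair, oxidative stress, heat shock, apoptosis, pluripotency, chromatin, imprinted and small RNA machinery genes.

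Without AAS replicate 2 no list was called in AAS embryos: the adjusted p was 0.0884 for ribosomal proteins (mean -0.32 against -0.93 with all libraries), 0.351 for oxidative phosphorylation (mean -0.26 against -0.56) and 0.815 for biogenesis (mean -0.0549 against -0.41). With AAE replicate 3 left out as well, which was chosen after seeing the data, the ribosomal protein list was called at the same mean (adjusted p = 0.0292). That library enters the comparison only through the shared estimate of spread. Over the omissions of 1 library the ribosomal adjusted p ranged from 2.57e-20 to 0.0884. Without control replicate 1 the biogenesis adjusted p was 0.243 and the ribosomal protein mean -0.56. AAS replicate 2 had a ribosomal protein score of -1.74 and a median correlation of 0.870 with the other libraries. The scores of AAS replicates 1 and 3, 0.0816 and 0.1208, lay within the control range of -0.4787 to 1.158. Of the 70 oxidative phosphorylation genes, 6, 16 and 5 were not listed in AAS replicates 1, 2 and 3 and were taken as 0, against 0, 1 and 1 in control and 4, 0 and 12 in AAE. Leaving out 1 library moved 9 of the 35 named genes by over 1.5 times. Without AAS replicate 2 Rps19 was at -1.30, Rpl5 at -1.21, Nop58 at -0.36, Ccng1 at -0.47, Ercc5 at -0.15 and Gm5662 at -0.35. Trp53inp1 was at 0.27 and Odf2 at -0.11 without AAS replicate 3, and Npm1 at -0.42 without control replicate 3. Quantile normalization moved the median of all genes from -0.11 to 0.02.

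**Figure D3:**
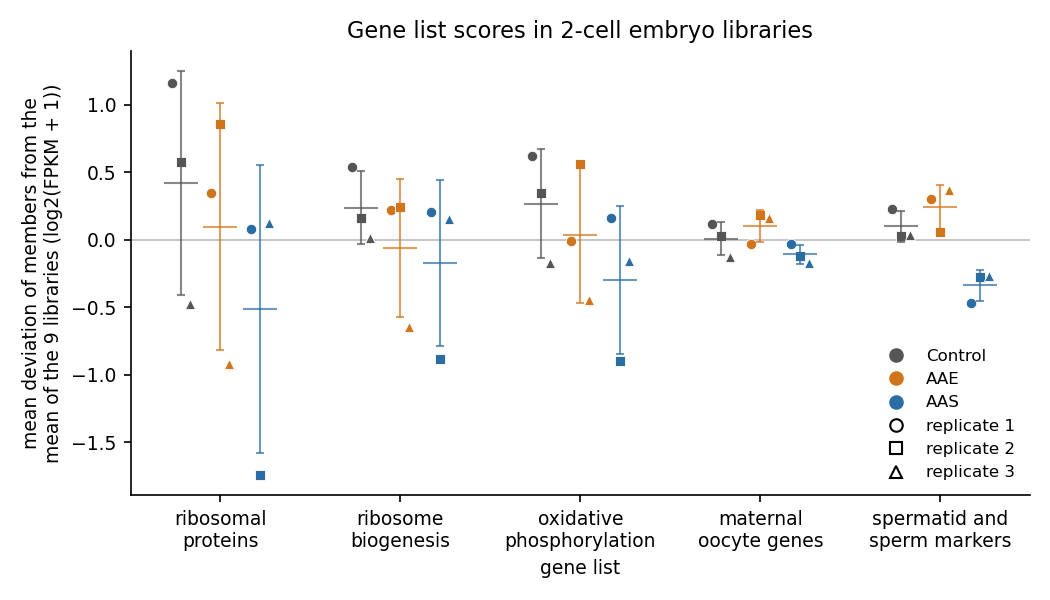
Mean deviation of list members from the mean of the 9 embryo libraries (log2(FPKM + 1)) for 5 gene lists; points are libraries, horizontal lines group means and bars the SD (n = 3). The ribosomal protein score ranges from -1.74 in AAS replicate 2 to 1.16 in control replicate 1, and control replicate 3 is at -0.48.

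The comparison of AAE with AAS embryos sets both exposures against each other, and the controls cancel. Sperm were collected 3 days after the last injection for AAE and 24 days after it for AAS. No collection time is given for the controls. A difference in effect therefore cannot be told apart from a difference in collection time. Immp1l (gene ID 66541), on chromosome 2 from 105904638 to 105965558 (GRCm38, RefSeq gene span), was at 198.5 ± 22.7 FPKM in AAE and 67.1 ± 1.94 in AAS (SD, n = 3 each), a log2 fold change of 1.55 (SE 0.198, adjusted p = 0.0710). Xrcc3 (gene ID 74335), a recombination repair gene on chromosome 12 from 111803192 to 111813893, was at 22.97 ± 8.80 against 3.85 ± 1.45 (2.28, SE 0.362). Mthfs of folate metabolism was at 20.9 ± 1.502 against 2.87 ± 1.71 (2.62), the myosin light chain Myl6 at 20.02 ± 8.33 against 2.94 ± 0.968 (2.37), and Swi5, a partner in recombination repair, at 117 ± 20.1 against 49.4 ± 16.7 (1.26). Vkorc1 (1.86), Fam162a (2.31), Ccl3 (2.37) and the kinase Mok (2.89) followed, where Ccl3 was not listed in AAS replicates 2 and 3, nor Mok in AAS replicate 2. Trappc2l was at 4.56, 2.94 and 5.36 FPKM in AAE and was not listed in any AAS library or in control replicate 2, which without counts cannot be read as a change. None passed: limma called 0 of 9766 genes, with 755 at an unadjusted p under 0.05 (540 higher in AAE, 215 lower) and 1100 without overlap (11.3%, chance 10%). The deposited table makes 55 calls, among them Immp1l, Xrcc3, Mthfs, Vkorc1 and Mok, and not Myl6, Swi5, Fam162a, Ccl3 or Trappc2l. Without control replicate 3, which enters only through the shared estimate of spread, 1 gene was called, Immp1l with an adjusted p = 0.0321.

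**Figure D4:**
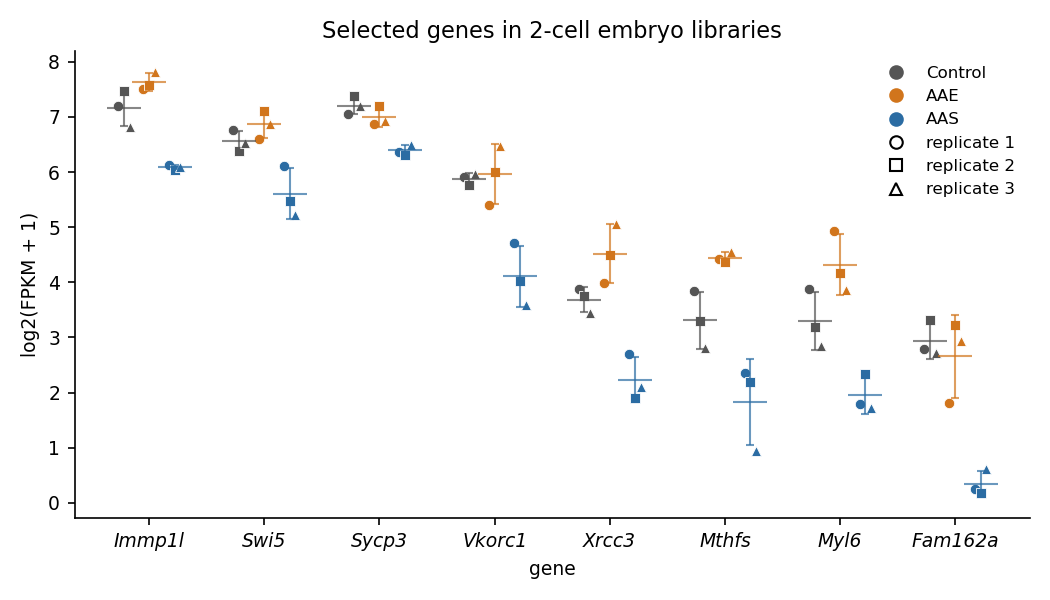
log2(FPKM + 1) of 8 genes per embryo library, taken from those with the smallest p in the AAS comparisons; points are libraries, horizontal lines group means and bars the SD (n = 3). Immp1l averages 198.5 FPKM in AAE, 144 in control and 67.1 in AAS.

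Relative to other genes, ribosomal protein genes were higher in AAE than in AAS embryos (median 0.59, 70 of 79 positive, adjusted p = 0.000118), with Rpl18 at 37.7 ± 10.3 against 14.6 ± 5.51 FPKM (SD, n = 3 each), and Rps19 at 1.88. Maternal oocyte genes were higher in AAE relative to other genes (median 0.18, 35 of 48 positive, adjusted p = 0.0331), with Zp1 of the egg coat at 32.6 ± 3.93 against 16.01 ± 2.51 FPKM (SD, n = 3 each), Dppa3 at 0.53 and Oas1d at 0.61. The estimated correlation was 0.767 for ribosomal proteins and 0.0567 for maternal genes, against the preset 0.01. With an estimated correlation the adjusted p was 0.967 for both lists, and fry gave 0.843 for ribosomal proteins and 0.3205 for maternal genes. With quantile normalization the maternal mean moved from 0.212 to 0.119 and its adjusted p to 0.1296, and with a mean of 5 FPKM or more its adjusted p was 0.0518. The ribosomal protein mean moved from 0.61 to 1.12 without AAE replicate 3 and 0.93 without AAS replicate 3. Without AAS replicate 2 the ribosomal protein mean was -0.00607 (adjusted p = 0.851), and without AAE replicate 2 no list was called, with an adjusted p = 0.404 for ribosomal proteins (mean 0.227) and 0.119 for maternal genes. The maternal adjusted p was 0.495 without AAE replicate 3 and 0.415 without AAS replicate 3. The number of lists called was 4 without AAS replicate 1, and 1 without AAS replicate 2 or AAS replicate 3. Oxidative phosphorylation (Cox5a at 1.06, Atp5f1 at 0.94, Ndufb6 at 2.03) and spermatid markers (Sycp3 at 0.60, Sycp1 at 0.68, Ldhc at 1.095 and not listed in AAE replicate 1 and AAS replicates 1 and 3) had an adjusted p = 0.0724 each, and fry gave 0.00269 for the spermatid markers, where Sycp3 and Sycp1 are genes of meiosis. Adjusted over the list alone, Xrcc3 and Sycp3 were called, 1 in each of their lists. In either direction, fry's mixed test gave an adjusted p = 0.0259 for DNA repair, with Blm at 0.62 and Neil3 at 0.52, and 0.0157 for chromatin genes. Among p53 targets Cdkn1a was at -0.94, Polk at 1.01 and Trp53inp1 at -0.53. The list adjusted p was 0.299 for mitosis, 0.368 for oxidative stress, 0.521 for DNA repair, 0.732 for apoptosis and cumulus markers, 0.895 for p53 targets, ribosome biogenesis and small RNA machinery, 0.976 for imprinted genes, 0.990 for 2-cell, heat shock, glycolysis and chromatin genes and 0.994 for pluripotency genes. Leaving out 1 library moved 7 of the 26 named genes by over 1.5 times. Without AAS replicate 2 Rps19 was at 1.13, Ndufb6 at 1.06, Sycp1 at 0.42 and Oas1d at 0.40, and Ldhc was at 0.31 without AAE replicate 3. Polk was at 0.63 without AAS replicate 1 and Trp53inp1 at -0.33 without AAS replicate 3. The chromatin list had a median of -0.02 and a mean of 0.05, and the imprinted list a median of -0.08 and a mean of 0.10.

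No gene was called in either exposure against control, so the overlap of calls in one direction could only be 0. At an unadjusted p under 0.05, 6 genes were higher and 29 lower in both, where independent lists would share 1.33 and 5.52, and both comparisons use the same control libraries. The fold changes correlated across genes at 0.324, which are not independent replicates, and 100 simulations of unchanged groups with each group's own variance gave 0.306. The covariance was 0.0740 against 0.0719 simulated, a difference of 0.00212. Without control replicate 3 the correlation was 0.492 and the covariance 0.148, and without AAE replicate 3 they were 0.194 and 0.0442. With AAS replicate 2 left out as well, chosen after seeing the data, the correlation was 0.185; the simulation was not repeated for these. With a pooled spread for all groups the simulations gave 0.499 and 0.112, and the group variances were chosen after that had been seen. The deposited tables call 15 genes for AAE, 35 for AAS and 55 between the exposures; 14, 31 and 46 of these were tested here, all with the same sign, and 11, 28 and 42 had an unadjusted p under 0.05.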

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

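All tests of explanations in this part were chosen after the results were seen; the list tests between AAE and AAS embryos were planned. A test of the difference between the exposures singled out 2 gene lists. Relative to other genes, ribosomal protein genes differed between AAE and AAS embryos (camera adjusted p = 0.0001179, median 0.59). So did maternal oocyte genes (adjusted p = 0.03314, median 0.18). Exposure stage and collection time cannot be told apart here. Both calls were lost with an estimated correlation (adjusted p = 0.967), and fry gave 0.843 and 0.3205. Without AAS replicate 2 the ribosomal mean turned from 0.61 to -0.00607 (adjusted p = 0.851), and without AAE replicate 2 it was 0.227 (adjusted p = 0.404). The maternal call was lost with quantile normalization (adjusted p = 0.1296, mean 0.119) and with a mean of 5 FPKM or more (adjusted p = 0.0518).

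Ribosomal protein and oxidative phosphorylation genes were lower in AAS embryos relative to other genes by camera at a preset correlation, with an adjusted p = 0.737 for both with an estimated correlation and 0.478 and 0.469 by fry. After removal of a trend with genomic span and level, the ribosomal mean went from -0.93 (SD 0.458 over 79 genes) to -0.6616 (SD 0.464, camera adjusted p = 3.40e-13 at the preset correlation). That of oxidative phosphorylation went from -0.56 to -0.34 (adjusted p = 0.00246, likewise). These values argue only against this fitted trend as the whole source. The removal was not repeated without AAS replicate 2 or at an estimated correlation. Ribosomal protein genes have a median span of 3164 bp against 26390 bp for all tested genes. Genomic span is not transcript length, so a bias with transcript length is not excluded. A single library may account for much of the pattern. Without AAS replicate 2 the ribosomal mean was -0.3175 (camera adjusted p = 0.0884, the highest over omissions of 1 library, with 2.57e-20 the lowest). Oxidative phosphorylation then had an adjusted p = 0.351. The ribosomal score was -1.744 in AAS replicate 2. In AAS replicates 1 and 3 it was 0.0816 and 0.1208, within the control range of -0.4787 to 1.158. With AAE replicate 3 left out as well the ribosomal list was called at the same mean (adjusted p = 0.0292). AAE replicate 3 enters this comparison only through the shared estimate of spread. The number of genes listed per library cannot be told apart from other sources, as its within-group relation with the score over 9 libraries gave r = 0.465 (exact permutation p = 0.282) and rho = 0.667 (p = 0.125), and r = -0.106 without the 2 libraries farthest from the median. A within-group relation also cannot see the gap between groups, where every AAS library listed fewer genes than every control library. Spermatocyte exposure stays open as an untested biological explanation.

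In AAE sperm the miRNA and snoRNA shares were higher. The higher miRNA share did not rest on AAE replicate 2 alone, since without it the ratio was 1.412. That both AAE libraries lay above both controls is the observation that raised the pattern and no separate test. The snoRNA share was 5.69% and 4.71% in AAE replicates 1 and 2 and 3.10% and 3.66% in control. With 2 libraries per group the exact permutation p cannot go below 0.333, so differences between single libraries are not excluded. With TMM factors, the mean of the epididymal list went from 0.467 to 0.0424 without AAE replicate 1. Summed as CPM over all counts, without these factors, the list was highest in AAE replicate 2, at 17132. It was at 13020 in AAE replicate 1 and at 5977 and 8222 in control. The value of 0.0424 therefore does not show that AAE replicate 2 lacks the higher share. A shift of the miRNA class as a whole may account for most list calls, since with miRNAs scaled to each other only 2 lists were called. RNA of epithelial or other somatic cells cannot be told apart from a change in sperm: the X-linked germ cell cluster had a ratio of 1.351, within the spread of the libraries, the epididymal, miR-200, leukocyte and red blood cell lists had 2.12, 2.06, 2.15 and 1.89, and the miR-34 and miR-449 family of germ and ciliated cells had 1.87. The red blood cell list rested mainly on miR-16-5p (541 and 719 counts in AAE) and the leukocyte list on miR-146b-5p (2135 and 1874). The leukocyte marker miR-142a-3p had 43 and 45 counts in AAE. Its log2 fold change was -0.1058 with miRNAs scaled to each other. The ratios of both lists are therefore no measure of blood cells. Epididymal exposure stays open as a biological explanation, untested apart from these.

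Linked inherited differences between the fathers may contribute to the genes that differ most between AAE and AAS embryos. Among the 100 genes with the smallest p, 13 pairs lay within 1 Mb of each other, against a median of 7 in 10000 random sets, a percentile of 94.69. The limit was a percentile of 95, so this cannot be told apart from chance placement, and neighbouring genes can also share regulation.

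The 10 splits of the 6 libraries of a comparison are too few for a share under 0.05. For single genes the real split gave 0 calls in each comparison, so all 10 splits gave as many, and the highest other split gave 1 for AAE against control, 0 for AAS against control and 7 for AAE against AAS. For gene lists, as many calls came from 2 splits for AAE against control (real 4, highest other 5), from 5 for AAS against control (real 3, highest other 5) and from 6 for AAE against AAS (real 2, highest other 4). The size of the ribosomal protein mean, looked at after the results were seen, was 0.3235 for AAE against control (highest other 1.215), 0.9324 for AAS against control (1.332) and 0.6089 for AAE against AAS (1.302).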

How the results depend on the processing

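The list tests with other pseudocounts, weights, median-centring, size factors, 2 groups alone or no filter, and those without both libraries of lowest correlation, were chosen after seeing the data; the other alternatives here were planned. The cause was not tested where none is given.

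Calls of sperm RNAs were 0, and 1 with library totals, 16 with no low-count filter (more RNAs tested) and 0 to 411 leaving out 1 library each. RLE factors, DESeq2, a mean count of 50, miRNAs alone and the replicate block gave 0. Of 12 sperm lists 8 were called; 0 with an estimated correlation, 2 with miRNAs alone, 2 to 11 leaving out 1 library, 8 with RLE factors and 11 with library totals, which moved the median of all RNAs to 0.36. With miRNAs alone the mean was -0.11 for the X-linked cluster, -0.0134 for the epididymal list and -0.11 for miR-142a-3p. Leaving out 1 library gave -0.0486 to 0.63 for the X-linked cluster and -0.21 to 1.019 for miR-142a-3p. The ratio of class shares ranged over 1.412 to 1.988 for miRNA, 1.39 to 1.68 for snoRNA and 0.919 to 1.21 for piRNA, and was 0.810 for the remaining entries without the top entry.

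Calls of embryo genes were 0 under all alternatives run, except 1 for AAE against AAS without control replicate 3, so leaving out 1 library gave 0 to 1 there; limma gave 111 to 1059 genes at an unadjusted p under 0.05 over these. Of the AAE against control lists 4 were called; 0 with an estimated correlation, 2 with no FPKM filter, 0 with array weights, 0 to 5 leaving out 1 library, and 0 without AAE replicate 3 and AAS replicate 2 together. Of the AAS lists 3 were called; 0 with an estimated correlation, 0 to 4 leaving out 1 library, and 1 without both. With no FPKM filter the AAS biogenesis adjusted p was 0.0617 and 2 lists were called. Between the exposures 2 were called, and 0 with an estimated correlation, 4 with no FPKM filter and 1 with a mean of 5 FPKM (maternal camera adjusted p = 0.0518). Leaving out 1 library gave 0 to 4, and leaving out both gave 1. Median-centring and array weights gave 3 each, and array weights gave 2 for AAS. The ribosomal protein mean in AAE against control was -0.77 to 0.18 leaving out 1 library and 0.18 without both, and between the exposures -0.00607 to 1.12. Quantile normalization ended the maternal call between the exposures (adjusted p = 0.1296). Overlap calls were 0 under each alternative, which was fixed because neither exposure had a call against control.

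The named genes and RNAs had 2024 alternative values: 2002 kept direction and side of the threshold, 19 passed it and 3 turned direction. None was called over all genes or RNAs with the main settings, so keeping its side means only staying uncalled. Leaving out an embryo library outside the comparison cannot move a fold change. The tally is therefore no measure of stable size. Leaving out a single library moved 15 of the 34 named sperm RNAs by over 1.5 times. For embryo genes it was 15 of 33 for AAE, 9 of 35 for AAS and 7 of 26 between them. The named lists had 249, of which 179 kept both, 63 lost the call and 7 turned direction.

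The replicate numbers were not taken as pairs: in embryos same-number correlations were -0.176 to 0.206 and 4 of 9 libraries correlated best with their own number; in sperm the correlation was 0.108 over all entries and 0.195 over those with a mean count of 50 or more, from 2 libraries per group. The replicate block moved the smallest adjusted p in sperm from 0.945 to 0.461 and gave 0 calls in each gene comparison (at unadjusted p under 0.05, 1395 sperm RNAs and 201, 582 and 737 embryo genes for AAE, AAS and between them), 10 sperm lists, and 0 overlap calls. Where 1 sperm library is left out, the lone sample is assumed to vary like the other group. The alternatives that need embryo counts were not run, since only FPKM are deposited. Sperm depth was 12810223 to 15356820 counts, and what it limits for RNAs with low counts was not separated from the spread between libraries.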

Other observations

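The RNA class sets in this part were chosen after seeing the data. Tested as sets with camera at a preset correlation, 7 of the 8 classes were called in sperm. Relative to other RNAs, miRNAs (adjusted p = 2.76e-16), snoRNAs (4.62e-15), snRNAs (0.000743) and miscellaneous RNAs (0.0307) were higher in AAE. Fragments of rRNA (4.43e-11) and tRNA (5.18e-07) were lower, and piRNAs (0.0439) were called lower at a median of -0.00794. With an estimated correlation none was called (adjusted p = 0.680 for snRNAs and 0.673 for the others), and fry gave 0.829 for each. The estimate was 0.0108 for piRNAs and ran from 0.141 to 0.876 for the other classes, against the preset 0.01. In the deposited sperm table, 59 miRNAs were higher and 2 lower at an unadjusted p under 0.05, 117 snoRNAs higher and 2 lower, and 3 tRNAs higher and 45 lower.

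Mean variance between replicates of log2(FPKM + 1) was 0.216 in control, 0.442 in AAE and 0.536 in AAS embryos. Of the deposited embryo calls, 7 of 15, 22 of 35 and 34 of 55 had a mean under 5 FPKM, and 4, 12 and 27 were not listed in a library of either group.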
